A study of Mus musculus with 2 samples.

How the data were processed

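The samples were extracellular vesicles (EVs), the membrane particles cells shed into their medium, from primary cortical astrocytes of newborn mice carrying an enhanced green fluorescent protein under the promoter of the astrocyte gene GFAP. Per the labels' protocols, IL-1β at 200 ng per ml, a cytokine released in brain inflammation, was added in vesicle-free medium. Per the same protocols, the medium was taken 2 h later and spun to remove debris before EVs were pelleted by ultracentrifugation. Per the series' design text, the control EVs were all particles released over 24 h. Treatment and collection time therefore changed together.

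RNA was measured with the NanoString nCounter assay, in which small RNAs are ligated to tags, hybridised to colour-coded reporter probes and counted one molecule at a time. Per the file headers, each deposited raw file holds reporter counts, with no normalization, for a rat miRNA code set. The labels give mouse as the organism. The code set has 420 miRNA probes, 8 negative controls, 6 positive controls, 5 spike-in probes for RNAs from other organisms, and probes for 4 mRNAs. Per the file headers, 1139 of 1150 fields of view were counted for IL-1β and 1121 of 1150 for the control, at binding densities of 0.18 and 0.13. The authors also deposited normalized signals for 124 miRNA probes, 5 of them with no IL-1β signal, and a ratio of IL-1β over control. How the signals were normalized is not given in the sources used here. The deposited value table holds the same signals as the authors' fold-change table.

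Each group held 1 sample, so no test across replicates was possible, and no p-value is given. Intervals cover counting error only, at 95% confidence. They are exact binomial (Clopper-Pearson) intervals for shares and for the split of a probe's count between the samples, and exact Poisson intervals for counts.

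A probe was taken as above background where its raw count exceeded the mean + 2 SD of the negative controls of the same sample, 9.67 counts for IL-1β and 6.41 for the control. Counts were scaled by the geometric mean of the 100 miRNA probes with the highest mean count, which gave a factor of 0.875 between IL-1β and control, with no background subtraction. Leaving background in the counts understates the change of probes with low counts. A probe above background in 1 sample only was given a bound against the other sample's threshold, and no fold where that bound fell on the wrong side of 1. For a named probe with 1 to 3 counts in the lower sample (miR-493), the ratio of the counts with its interval is printed in place of the bound. Probes called higher or lower were at least 2-fold apart, or bounded so, with an interval that excluded 1. Named miRNAs were, among probes above background in at least 1 sample, the 10 highest counts of each sample, and the 12 largest and 12 smallest ratios whose interval excluded 1. From each list, up to 4 members with the highest mean count were added.

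The 22 miRNA lists, the comparisons, the naming rule and the first set of alternatives were fixed before the data were examined. The lists covered inflammation-responsive miRNAs, miRNAs reported to target PPARα, cell types (astrocyte, neuron, microglia and leukocyte, oligodendrocyte, endothelial, mural and fibroblast, erythroid, hepatocyte, muscle, epithelial), the let-7, miR-29, miR-30 and miR-15/16 families, and the miR-17-92, miR-23-27-24, miR-290-295, miR-302-367, Dlk1-Dio3 and Sfmbt2 clusters. They were written with mouse names and matched to the rat probe names by the same rule. A list's median log2 ratio over at least 3 valued members was placed among 10000 random lists of the same size, matched on mean count in 5 strata. Random lists were drawn from all valued probes, including those with no mouse counterpart (defined below). Above background in both samples, these had a median ratio of 1.30 against 1.14 and a log2 SD of 0.486 against 0.792 for the others. Their higher median can make low percentiles too extreme, and their smaller spread can do so for low and high percentiles alike.

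A probe was counted as having a mouse counterpart where a mouse miRNA gene of RefSeq's GRCm38.p6 annotation shares its number, which held for 351 of the 420 probes. The other 69, mostly rat miRNAs such as miR-3583-3p, served as a second view of background, chosen after seeing the data. The names of 3 probes (miR-208, miR-290, miR-466c) carry a factor above 0, read here as the share of the strongest positive control to be subtracted as probe background. The subtraction was made only as an alternative.

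Alternatives were scaling on positive controls, on total miRNA count, on the median ratio or none, subtraction of the negative-control mean, other background thresholds and filters, and fold minimums of 1.5 and 4. Those added after seeing the data were scaling or thresholds from probes with no mouse counterpart, only probes with one, more scalings for the lists, the factor in the probe name and the authors' normalized signals. The procedure was tested on simulated data drawn from the mean counts of these 420 probes, 60 of them changed, in 50 runs. These draws, and those for the lists below, held counting noise only. Their rates therefore leave out differences between preparations and error in the scaling. Of probes with a mean count of 20 or more, 89.4% of 2.5-fold changes and 99.7% of 4-fold changes were called, against 0.614% of unchanged ones. Below a mean of 20 counts, the calls fell to 9.71% at 2.5-fold and 18.2% at 4-fold, against 0.375% of unchanged probes. In 40 runs over the 420 probes, a simulated list of 6 probes raised 2.5-fold passed the 97.5th percentile in 100% of runs. Its members were drawn only from probes with a mean count of 20 or more. Lists with fewer valued members or lower counts were not simulated. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 were used.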

Results

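The study set the miRNA content of EVs that mouse astrocytes released within 2 h of IL-1β stimulation beside that of EVs accumulated over 24 h without it. Each group held 1 sample, so no difference below has a replicate check, and each ratio compares these 2 preparations. The 420 miRNA probes of the rat code set summed to 13514 counts in the IL-1β sample and 16812 in the control sample. The median probe had 5 counts in both samples.

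The highest count in both preparations was that of miR-125b-5p, a miRNA abundant in brain. It made up 10.9% of the miRNA counts in IL-1β EVs (95% CI 10.4 to 11.5, 1478 counts) and 9.87% in control EVs (9.43 to 10.3, 1660 counts). In the control, miR-22 (5.49%), miR-181a (4.71%), miR-145 (4.61%) and let-7b (4.21%) followed. In IL-1β EVs, the next were miR-466c (4.44%), miR-125a-5p (3.97%), let-7b (3.36%), let-7d (3.09%) and miR-145 (2.94%). There miR-22 ranked 8th at 2.36% (2.11 to 2.63), let-7c 7th at 2.72% and miR-24 10th at 1.94%, while miR-181a ranked 12th and miR-1224 moved from rank 9 in the control to rank 40. The control's 10 highest also included miR-125a-5p, let-7d, miR-466c, miR-1224 and miR-199a-3p. The miR-466c probe is one whose name carries a background factor, and subtracting it took the count from 600 to 364 in IL-1β EVs, below let-7c at 367, and from 486 to 321 in the control. The probe miR-3583-3p, 9th in IL-1β EVs at 2.00%, has no mouse counterpart. The 10 highest probes held 37.7% of the counts in IL-1β EVs (36.9 to 38.6) and 43.4% in control EVs (42.7 to 44.2).

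Above background were 146 of the 420 probes (34.8%) in IL-1β EVs and 185 (44.0%) in control EVs, 139 of them in both. Of the probes with no mouse counterpart, 41 of 69 (59.4%) and 49 of 69 (71.0%) also passed, against 105 of 351 (29.9%) and 136 of 351 (38.7%) of the others. With the 95th percentile of the probes with no mouse counterpart as the threshold, 29 and 35 probes passed. The threshold of the IL-1β sample was raised by 1 negative control at 10 counts.

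Relative to the 100 highest probes, miR-1224, miR-132, miR-204, miR-30c, miR-100, miR-181a, miR-22 and the miR-27 pair were lower in IL-1β EVs, and let-7a and let-7c were higher. Among probes above background in both samples, the largest decrease was in miR-1224, 86 counts against 473, a 4.81-fold difference (95% CI 3.82 to 6.13). Of the 160 probes with a ratio or bound, 9 were at least 2-fold higher and 15 at least 2-fold lower. The balance of higher and lower calls depended on scaling: 0 higher and 46 lower with positive controls, 15 and 14 with total counts, 2 and 24 with the median ratio, and 4 and 21 with none. Against the main scaling, these moved every log2 ratio by -0.78, 0.12, -0.27 and -0.19.

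Among the lower miRNAs, miR-132, which responds to neuronal activity and to inflammatory signals, fell 3.91-fold (2.11 to 7.77) from 58 to 13 counts. The choroid plexus and pigment epithelium miRNA miR-204 fell 3.68-fold (2.52 to 5.52), miR-100 3.16-fold (2.5 to 4.04) and miR-181a, with 792 control counts, 2.84-fold (2.46 to 3.29). The fall of miR-22, from 923 to 319 counts, was 2.53-fold (2.23 to 2.89). The miR-25 ratio was 0.424 (0.275 to 0.638). Bounds against background were given for miR-345-5p (8 against 33 counts, at least 2.99-fold lower), miR-1949 (5 against 29, at least 2.63-fold) and miR-411 (7 against 28, at least 2.54-fold). The miR-290 probe gave 65 against 178 counts, a ratio of 0.417 (0.309 to 0.557), but with its name's factor subtracted the IL-1β count fell below 0.

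On the higher side, let-7a rose 3.43-fold (2.5 to 4.75) from 54 to 162 counts and let-7c 2.14-fold (1.79 to 2.56) from 196 to 367. The let-7c log2 ratio fell below 2-fold with no scaling (0.90), the median ratio (0.82), probes with no mouse counterpart (0.74) and positive controls (0.31). That of let-7a did so only with positive controls (0.99) among these. The other 7 calls had lower counts. They were miR-504 (28 against 13 counts, ratio 2.46, interval 1.23 to 5.17), miR-342-5p (22 against 11, ratio 2.28, interval 1.06 to 5.22), and the bounds miR-329 (15 against 5, at least 2.67-fold higher) and miR-802 (14 against 5, at least 2.49-fold). The remaining 3, miR-3577, miR-3558-5p and miR-3581, have no mouse counterpart and ratios of 2.40, 2.39 and 2.24. Just under 2-fold, miR-29b was at 1.99 (1.16 to 3.48) and let-7e at 1.98 (1.38 to 2.88). The miR-493 probe had 11 against 2 counts, the latter below background, a ratio of 6.28 with an interval of 1.37 to 58.3.

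**Figure D1:**
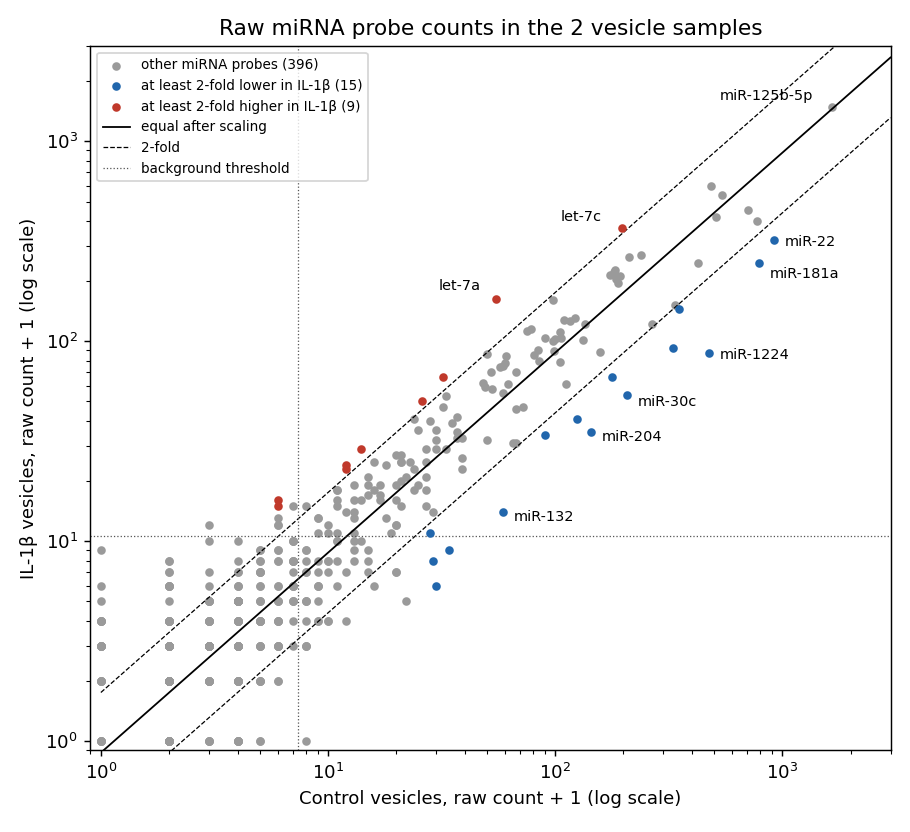
Raw count + 1 of each miRNA probe in the control (horizontal) and IL-1β (vertical) EVs, both on log scales, 1 sample each. The solid line marks equal scaled counts, dashed lines 2-fold differences and dotted lines the background thresholds. The 15 lower calls (blue) include miR-1224, at 86 against 473 counts, and the 9 higher calls (red) include let-7a, at 162 against 54.

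The let-7 family, inhibitors of growth genes expressed in many differentiated cells, leaned higher: its median log2 ratio was 0.54, at the 98.8th percentile of random lists, and turned to -0.25 with positive-control scaling. Of its 8 probes, let-7a and let-7c were called, while let-7b had a ratio of 0.733 (0.650 to 0.825) and let-7d 0.934 (0.819 to 1.07). With positive-control scaling the family had the 99.1st percentile, since its rank does not depend on the common shift. Members differ by few bases, so part of one member's count can come from another.

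The miR-30 family, highly conserved and broadly expressed, was lower in all scalings, with a median log2 ratio of -1.24 at the 2.75th percentile over 3 valued members. Of these, miR-30c fell 3.40-fold (2.5 to 4.69) and miR-30b-5p had 10 against 27 counts, a ratio of 0.423 (0.183 to 0.902). The third, miR-30d, had a ratio of 0.536 (0.335 to 0.839), and miR-30a, with 3 against 11 counts, was given no fold. The miR-23-27-24 clusters had a median of -1.03 (percentile 3.69) and split: miR-27a was at 0.471 (0.385 to 0.574), miR-27b at 0.369 (0.251 to 0.530) and miR-23a at 0.510 (0.418 to 0.620). The miR-24 probe was at 1.43 (1.18 to 1.72), a direction that turned with positive-control scaling.

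The astrocyte list was split, with 6 of its 11 valued members below a ratio of 1 and 5 above it. Its median log2 ratio was -0.94, at the 0.655th percentile, and stayed negative in all scalings, which moved ratios up by 0.12 at most. Of the members, 4 were called lower (miR-100, miR-181a, miR-27a, miR-27b) and 0 higher, but miR-27a fell short of 2-fold with total-count scaling (log2 ratio -0.96). The median was the value of miR-99a, at 0.522 (0.417 to 0.649), and the next member up, miR-125b-5p, had a ratio of 1.02 (0.948 to 1.09). The median and its percentile therefore hinge on which side of this gap the middle member fell. Under 2-fold but with intervals above 1 were miR-29b at 1.99 (1.16 to 3.48), miR-24 at 1.43 (1.18 to 1.72) and miR-29a at 1.26 (1.03 to 1.55), the last pair turning with positive-control scaling. The PPARα list, aimed at a nuclear receptor of lipid metabolism and inflammation, had 4 valued members, all below 1, and a median of -1.21 (percentile 0.980). Its 3 lower calls were miR-22, miR-27a, which total-count scaling ended, and miR-27b, the last pair shared with the astrocyte and miR-23-27-24 lists. Its other valued member, miR-21, had a ratio of 0.740 (0.499 to 1.09). That list was drawn from general knowledge of the subject, and is no independent evidence of a direction here.

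Inflammation-responsive miRNAs with a value did not move together: the median was 0.02 (percentile 27.2) over 7 valued members of 17 probes. That median was below 0 with every other scaling but total counts, and miR-132 was the 1 call. The list's other probes, among them miR-146a (3 against 5 counts), were below background in both samples. A fall of theirs, or a rise that stayed below the IL-1β threshold of 9.67 counts, could not be seen. Of that list, miR-125a-5p was at 1.13 (0.997 to 1.27), miR-125b-5p at 1.02 and miR-21 at 0.740, and miR-146b had 6 against 19 counts. The miR-29 family, targeting collagen genes, had a median of 0.35 (percentile 70.9), with miR-29a at 1.26 (1.03 to 1.55) and miR-29c at 1.28 (0.783 to 2.09). The miR-29 median turned to -0.43 with positive-control scaling, and fell just below 0 with scaling on probes with no mouse counterpart. The miR-17-92 clusters had a median of -0.41 (percentile 3.15), with miR-25 as the 1 call and miR-20a/20b-5p at 0.723 (0.446 to 1.16), miR-93 (8 against 14 counts) and miR-363 at 1.24 (0.521 to 2.97). The imprinted Dlk1-Dio3 cluster had a median of 0.51 (percentile 95.2) over 13 valued probes, of which miR-329 was called higher and miR-411 lower. In that cluster miR-544 was at 1.40 (1.15 to 1.72), miR-543 at 1.46 (1.02 to 2.09), miR-540 at 1.22 (0.712 to 2.1) and miR-154 at 1.00 (0.580 to 1.71). That median turned to -0.26 with positive-control scaling. The Sfmbt2 cluster had a median of 0.22 (percentile 42.0), with miR-466c at 1.41 (1.25 to 1.59), miR-466d at 1.17 (0.872 to 1.56) and miR-466b at 1.06 (0.720 to 1.57), and it turned negative with positive-control, median-ratio scaling and scaling on probes with no mouse counterpart.

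Of the lists for other cell types, mural cell and fibroblast miRNAs had a median of -0.60 (percentile 12.8) with no calls. Among them, miR-145 was at 0.585 (0.517 to 0.661), miR-199a-3p at 0.661 (0.563 to 0.776), miR-199a-5p at 0.633 (0.481 to 0.828) and miR-214 at 1.21 (0.916 to 1.595). Muscle miRNAs had a median of -0.60 (percentile 9.66) with no calls, over miR-1 (11 against 19 counts), miR-206 (28 against 26) and miR-208b-3p (14 against 26). Too few members had a value for the neuron list (1, miR-132), the microglia and leukocyte list (2, miR-142-3p at 0.952 and miR-342-5p), and the oligodendrocyte list (2, miR-23a and miR-32 at 0.857). The same held for hepatocyte (1, miR-122, 5 against 15 counts), the miR-15/16 family (2, miR-16 at 1.12 and miR-15b at 1.25) and the miR-290-295 cluster (2, miR-290 and miR-293 at 1.56). The endothelial list (miR-126, 7 against 10 counts), the erythroid list and the epithelial list had 0 valued members, and 0 probes of the miR-302-367 cluster were on the code set.

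**Figure D2:**
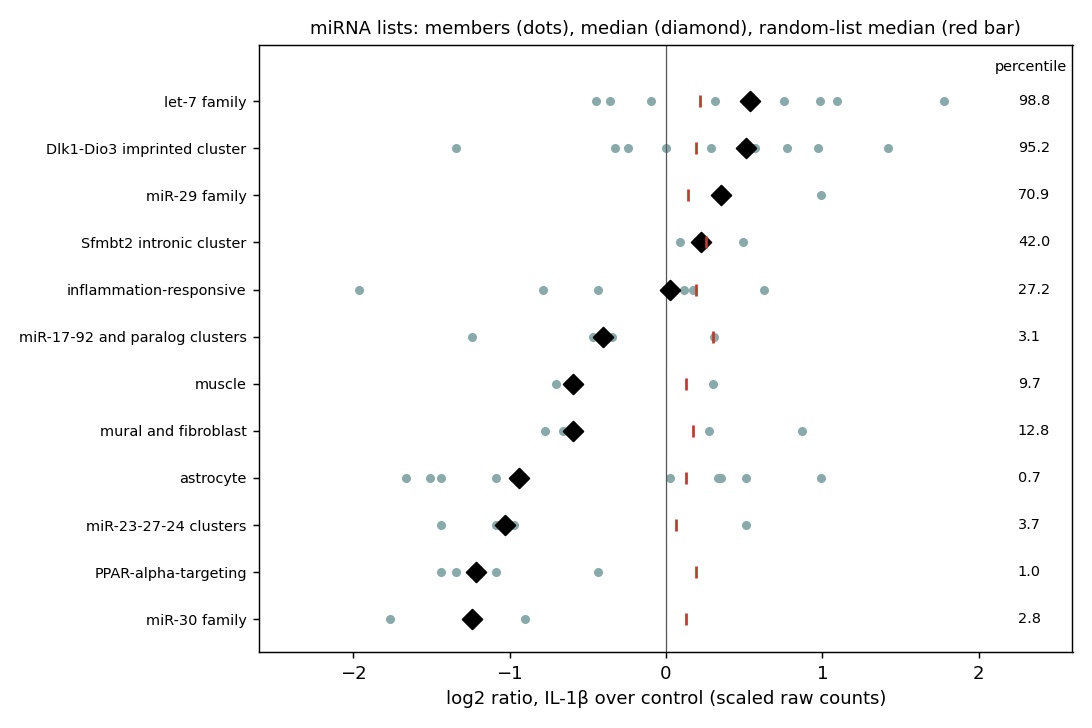
Log2 ratio of IL-1β over control EVs for the members (dots) of the 12 lists with at least 3 valued members, with the list median (diamond), the median of random lists (red bar) and the list's percentile at the right. The let-7 family lies at the 98.8th percentile and the astrocyte list at the 0.655th. With positive-control scaling each member shown moves by -0.78, and the let-7, Dlk1-Dio3, miR-29, Sfmbt2 and inflammation medians turn negative. The miR-30 and Dlk1-Dio3 medians then rest on 4 and 14 members, so they move by other amounts.

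The authors' deposited table orders the miRNAs differently. In it the largest increases were miR-99b (ratio 6.50), let-7f (4.19), miR-324-5p (3.48), miR-34c (3.47), miR-16 and miR-214 (both 2.76), and the largest decreases miR-29b (0.32), miR-106b (0.34), miR-290 (0.35), miR-30a (0.36) and miR-144 (0.38). Over the 119 probes with both deposited signals, 11 were at least 2-fold higher and 10 at least 2-fold lower. Across the 101 miRNAs with a ratio from both sources, Spearman's rho was -0.0258 and 45 (44.6%, exact binomial CI 34.7 to 54.8) had the same direction, as a description, since miRNAs are not independent replicates. The raw counts put miR-99b at 0.618, and the sources also differed in direction for miR-100 (2.05 deposited, 0.316 raw), miR-1224 (1.27 against 0.208) and miR-29b (0.319 against 1.99). Of the 18 called probes the table lists, 13 had the same direction, among them let-7a (1.24), let-7c (1.49), miR-22 (0.726), miR-181a (0.753), miR-27a (0.620) and miR-30c (0.550). The 13 were 10 of the 15 lower calls and 3 of the 3 higher calls. Deposited ratios leaned below 1 (median 0.883 over 119 probes), so part of the agreement of lower calls can come from that lean. Of the 101, the deposited signals put 9 at least 2-fold higher and 6 lower, and the raw counts called 3 higher and 15 lower. Shared were 2 lower calls (0.891 by chance) and 0 higher (0.267 by chance). From the deposited signals, the list medians of log2 ratios were 0.14 for the miR-23-27-24 clusters, -1.32 for the miR-29 family and -0.43 for the Dlk1-Dio3 cluster, opposite in sign to the raw counts. The members differed, 5, 3 and 4 with deposited signals against 4, 3 and 13 with raw values, so only the miR-29 medians rest on the same miRNAs. The astrocyte list stood at -0.06, the mural and fibroblast list at -0.03, the miR-30 family at -0.33, the PPARα list at -0.46, the miR-17-92 clusters at -0.58 and the let-7 family at 0.37. The inflammation list stood at 0.20 and the Sfmbt2 cluster at 0.09. The table lists a ratio of 0 for 4 probes that have both signals, so ratios here were taken from the signals.

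**Figure D3:**
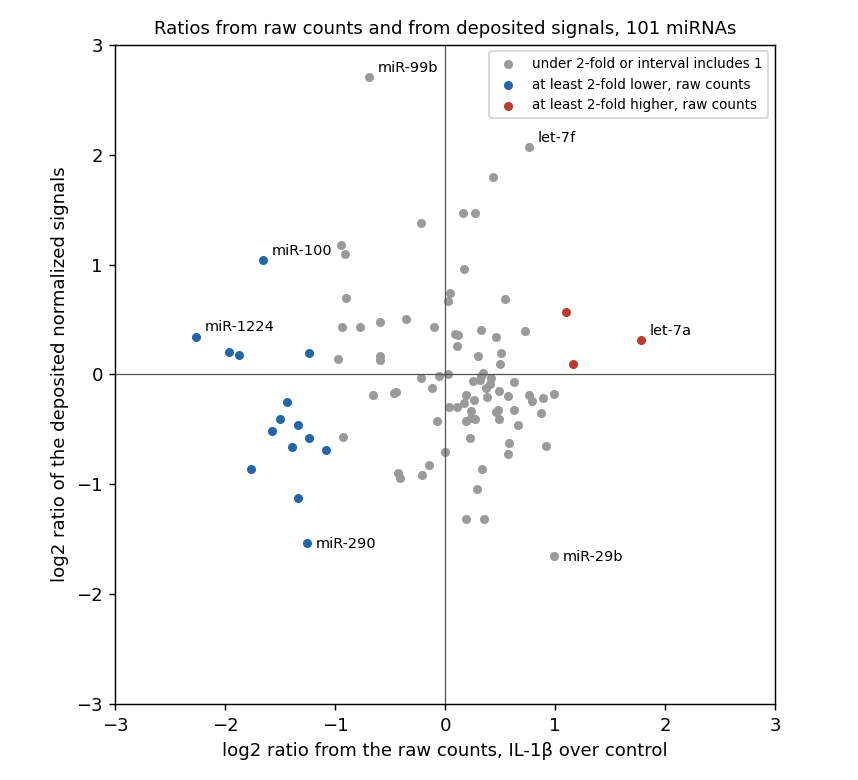
Log2 ratio of IL-1β over control from the raw counts (horizontal) and from the authors' deposited signals (vertical) for 101 miRNAs. Blue and red mark the probes called lower and higher from the raw counts; Spearman's rho was -0.0258, and miR-100 and miR-1224 lie in opposite directions in the 2 sources.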

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

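The tests in this part were chosen after the values were seen. The code set also carries probes for 4 mRNAs, which enter no comparison above, and all gave more counts in the IL-1β EVs. On the same scaling as the miRNAs, Actb was 63.3-fold higher (95% counting CI 58.3 to 68.9, 31319 against 565 counts), Gapdh 34.8-fold (30.04 to 40.5), Rpl19 7.49-fold (6.63 to 8.50) and B2m 5.79-fold (4.79 to 7.05). Scaled on positive controls, they were 36.8-, 20.2-, 4.35- and 3.36-fold higher.

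A lane-wide difference in counting is argued against: the positive controls differed by 1.51-fold, below the smallest raw mRNA ratio, 5.07. More RNA of every kind in the IL-1β preparation is argued against as well, since the summed miRNA counts stood at 0.804 of the control's. Treatment, the shorter collection and RNA from broken cells stay open, because each group is 1 sample and the collection times differ. Spike-in probes, at 14 and 12 counts in sum over 5 probes, give no independent scale.

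The authors' signals do not rank the miRNAs as the raw counts do, and the tables argue against a simple account. A rank-preserving normalization of each sample's raw counts would leave rho near 1 between signal and count, and the higher rho was 0.531 (resampling probes, 0.381 to 0.662). Order was kept better within each probe set. Over 100 probes with a mouse counterpart, rho was 0.609 in IL-1β EVs and 0.598 in the control. Over the 19 with none, it was 0.818 and 0.903. The median deposited signal over raw count was 5.35 in IL-1β and 3.33 in control EVs for probes with a mouse counterpart. For those with none it was 0.592 and 0.732, so 1 scale factor per sample does not link signals and counts. Of the 124 listed probes, 12 were below background in both raw samples. Of the 296 not listed, 80 were above it in at least 1 sample. Exchange of the raw count files with the order kept would leave crossed rho values near 1. The higher crossed rho, IL-1β signal against control count, was 0.588 (0.459 to 0.698). With the raw files ranking alike (rho 0.914), the same-sample rho already capped that crossed rho at 0.799. It was bound to fall short, so it adds no test of exchange. Both signals followed the control count more closely than the IL-1β count, with overlapping intervals. For the IL-1β signal, rho was 0.588 against 0.488, and for the control signal 0.531 against 0.438. Exchange together with a change of order stays open. Another hybridisation of the same code set may underlie the signals, which would keep the order of probes with no mouse counterpart better than that of the others. The rho difference was 0.306 (0.0806 to 0.480) in the control and 0.208 (-0.152 to 0.437) in IL-1β EVs, so this stays open.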

How the results depend on the processing

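Alternatives based on probes with no mouse counterpart, on probes with one, and on the authors' normalized signals, the subtraction of the factor in the probe name, and scalings of the lists other than positive controls and total counts were chosen after seeing the data. Counts of calls depended on scaling, the fold minimum and the background threshold. Positive-control scaling gave 0 higher and 46 lower miRNAs, total-count scaling 15 higher, median-ratio scaling 2 higher and 24 lower, and no scaling 4 higher. Scaling on probes with no mouse counterpart gave 1 higher and 27 lower. Total-count scaling, which moves ratios up, kept 14 of the 15 lower calls and ended that of miR-27a (-0.96). Positive-control, median-ratio and no scaling, which move ratios down, kept 0, 2 and 4 of the 9 higher calls. With no filter there were 14 higher calls. A fold minimum of 1.5 gave 19 higher and 26 lower, and one of 4 gave 0 and 1. Above the 95th percentile of probes with no mouse counterpart, 29 probes passed in IL-1β and 35 in control EVs, with 1 higher and 5 lower calls. The share of the 10 highest miRNAs rose to 40.8% and 46.2% with the negative-control mean subtracted, since subtraction removes low counts.

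Among named miRNAs whose interval excluded 1, positive-control scaling turned the log2 ratio of miR-24 (-0.27), miR-29a (-0.45), miR-3583-3p (-0.41), miR-466c (-0.29), miR-543 (-0.24) and miR-544 (-0.29), by its common shift, and a further 13 whose interval included 1. Of the list medians it turned 5, that of the let-7 family (-0.25) and those of the Dlk1-Dio3, miR-29, Sfmbt2 and inflammation lists. Scaling on probes with no mouse counterpart turned miR-29a (-0.019), 12 whose interval included 1 and 3 list medians (inflammation, miR-29 and Sfmbt2). Total-count scaling turned 3, median-ratio scaling 5 and no scaling 4, in each case with an interval that included 1. Median-ratio scaling also turned 2 list medians (inflammation and Sfmbt2) and no scaling 1 (inflammation). The authors' normalized signals turned 3 list medians, in part over other members, 5 log2 ratios whose interval included 1 and 14 whose interval excluded it: let-7e (-0.18), miR-100 (1.04), miR-1224 (0.35), miR-132 (0.20), miR-145 (0.43), miR-199a-3p (0.13), miR-204 (0.18), miR-23a (0.14), miR-29a (-0.86), miR-29b (-1.65), miR-30b-5p (0.20), miR-30d (0.69), miR-3583-3p (-0.12) and miR-544 (-0.15). The cause was not tested beyond the rank comparisons above. Turns of a ratio whose interval excluded 1 were counted apart. Of the other values of named miRNAs, 558 stayed within their counting interval and 103 moved outside it. The 558 include 54 from the filter on both samples and 58 from probes with a mouse counterpart, settings that cannot change a ratio. They also include 62 each from no filter and from the highest negative control as threshold. Those settings can change only bounds, not ratios of probes above background in both samples. Subtracting the factor in the probe name left miR-208 with no positive count and miR-290 none in IL-1β EVs, so no ratio could be had. No paired analysis was possible because each group held 1 sample. Depth limits probes under 20 counts, where few simulated changes were called.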

Other observations

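In the mouse genome, 3 clusters each hold a miR-99 or miR-100, a let-7 and a miR-125 gene, and within each the let-7 ratio lay above 1 and the miR-99 or miR-100 ratio below 1. This was noticed after the values were seen. With miR-100 and let-7a, neighbours on 1 chromosome, the let-7 ratio was 10.8 times the miR-100 ratio (95% counting interval, Wald on the log scale, 7.38 to 15.95). For let-7c and miR-99a it was 4.10 times (3.11 to 5.41), with miR-99a at 0.522 (121 against 265 counts), and for let-7e and miR-99b 3.21 times (2.00 to 5.14). Their miR-125 partners, miR-125b-5p and miR-125a-5p, were at 1.02 and 1.13. These quotients need no scaling, but the deposited signals gave 0.605, 1.1 and 0.136 in the same order. Mature let-7a, let-7c and miR-125b also come from other genes.

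Probes with no mouse counterpart often counted above the negative controls, and their ratios varied little. A candidate explanation is probe background that does not follow the sample's miRNA, a test chosen after the values were seen. Over the 40 such probes above background in both samples, the variance of log ratios was 1.46 times that from counting (0.898 to 2.06 on resampling probes). That of the 85 others in the same count range was 6.73 times. The interval reaches past the bound of 2 set for background alone, so the question stays open. Above the 95th percentile of these probes, 25 and 31 of the 351 other probes passed in IL-1β and control EVs.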
